A study of Homo sapiens with 30 samples.

How the data were processed

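RNA sequencing values of 22 libraries in 11 groups of 2 were analysed. The other 8 samples of the series (methylated DNA and chromatin immunoprecipitation) were not analysed here. The deposited values are FPKM in the first deposit (fragments scaled by transcript length and library size; 12 libraries, 1 of them with a column headed RPKM), as computed by the authors. The 10 files of the second deposit were named RPKM by the authors and have a column headed FPKM. The submitters' processing notes name FastQC, Bowtie2, TopHat, Cufflinks 2.0.2 and SAMtools, and the hg19 build. Their settings, the annotation release, any scaling between libraries and the rule for listing genes are not given in the sources used here. Depth per library is unknown, as the values are not counts.

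Values were matched by Ensembl gene ID, version suffixes removed, and summed per gene symbol as given in the files. Of 19362 IDs in the first deposit 19255 were in the reference table of gene names, and of 60684 in the second 56538. Files of the first deposit list 13216 to 19362 genes, and those of the second 60639 to 60674. A gene that a file does not list was treated as having no value, not as 0. One entry of the 5-Aza libraries of B2-1 (POLR2A, replicate 1) was not a number and was left out. The replicate numbers of those libraries follow the titles.

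Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on log2(value + 1), with a mean per group and no other term, in 1 fit per deposit so that all groups share the estimate of the spread. Genes entered with a value of at least 1 in at least 2 libraries of the fit. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 change of at least 1. The 10 comparisons were siCse1l, siKpnb1, 5-Aza, TSA and SAHA with control, SAHA with TSA, and siCse1l with siKpnb1 in B2-1 cells of the first deposit, and siNova1+siHdac1/2 with siHdac1/2 in B2-1 and siCse1l and 5-Aza with untreated cells in HCT116 of the second. Groups of different deposits were compared directly in only 1 test, of the B2-1 control libraries against the siHdac1/2 libraries in hypoxia-response genes. The differences between B2-1 and HCT116 of the siCse1l and of the 5-Aza effect were tested as interaction contrasts in 1 fit over genes that passed the filter in both deposits.

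The 24 gene lists were fixed before any value was seen: perturbation targets, autosomal germline genes, X-linked cancer-testis families, imprinted genes, DNA methylation machinery, HDACs and corepressors, nuclear transport, interferon-stimulated genes, p53 targets, S phase, G2/M phase, cholesterol synthesis, unfolded protein and amino acid stress response, heat shock, neuronal genes, histone genes, metallothioneins, immediate early genes, genes reported hypermethylated in colorectal cancer, colon epithelial genes, embryonic kidney genes, fibroblast genes, blood genes and ribosomal proteins. A list of 36 hypoxia-response genes was made after the values were seen. Lists with at least 5 tested members were tested against all other genes with limma's cameraPR (preset correlation 0.01) and again with camera and an estimated correlation over genes with a value in all libraries of the deposit, adjusted over the lists of a comparison. Overlaps were set against independent calls and, where comparisons share controls, against 20 simulated data sets with no effect and against fits with 1 control library for each comparison. The 95% intervals of the differences between SAHA and TSA are those of the limma fit, and the other intervals are from resampling genes.

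Genes named in the text follow a rule fixed before any value was seen: the knocked-down genes, the 10 largest rises and 10 largest falls among called genes whose groups do not overlap (5 and 5 for SAHA against TSA and siCse1l against siKpnb1), and up to 4 members per list with the smallest adjusted p, less some left out for space. One gene that the rule selects is not reported here. Left out of the largest changes were small and long noncoding RNAs known by their symbol prefix, loci without a gene name or with an open reading frame symbol, mitochondrial transcripts, entries that pool symbols, and sex-linked marker genes.

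The method was tested on simulated values with the spread of the data. For siCse1l in B2-1 it called 54% of planted log2 changes of 1 and 100% of those of 1.5, 2 and 3, with 0 false calls among 13374 genes, and in HCT116 42%, 98%, 100% and 100% with 3 false calls among 17643. For the difference between lines it called 64% at 1 and 100% above, with 0 false calls among 12945 genes. Of 200 lists of unchanged genes, 0% and 2% had an unadjusted p under 0.05. Genes were simulated as independent of each other, so this does not show the error rate of the set test for lists whose genes vary together.

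The alternatives tried were a pseudocount of 0.1, no filter, a filter at 5, no minimum change, quantile normalization, median ratio scaling, rescaling without mitochondrial transcripts, replicate number as a block, a fit of only the 2 groups compared, and leaving out each library in turn. Quantile normalization had been planned with limma's function. Because files list different genes it was replaced by a mapping built on the genes with a value in all libraries and applied to the others by interpolation. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for reading, counting and drawing.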

Results

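Gene expression was measured by RNA sequencing in 22 libraries that fall into 11 groups of 2. Of these, 12 libraries from a first deposit came from B2-1 cells, a HEK-293 (human embryonic kidney) line with an integrated CMV-GFP reporter that is methylated. Its groups were control cells, cells given small interfering RNA against CSE1L (siCse1l) or KPNB1 (siKpnb1), and cells treated with 5-Aza (an inhibitor of DNA methyltransferases) or with TSA or SAHA (related hydroxamate inhibitors of histone deacetylases). The other 10 libraries, from a second deposit, held B2-1 cells with siHdac1/2 or siNova1+siHdac1/2, and HCT116 (colon cancer) cells left untreated, given siCse1l or treated with 5-Aza. Per the labels, the series asks what part CSE1L has in keeping genes silent. CSE1L is the export receptor that returns importin alpha from the nucleus, and KPNB1 (importin beta) carries cargo the other way.

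Values are FPKM, so the depth behind each is unknown. Per library they summed to 421048 to 511504, and mitochondrially encoded transcripts took 6.22 to 21.6% of that total. All means are given ± SD with n = 2 libraries, and a number after a gene in parentheses is its log2 change ± SE on the log2(FPKM + 1) scale, which understates changes of genes with low values. Genes were called at an adjusted p (limma) under 0.05 with a log2 change of at least 1. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. The files of the first deposit list different sets of genes. The control files list the same genes as the SAHA files, and a gene that is not listed has no value and was not tested. Labels give no dose or time of any treatment, and the control group is labelled only as B2-1 cells. An effect of transfection or of a solvent is therefore part of each comparison with it. A value of exactly 0 can be a failed estimate (MT-CO1 was listed at 0 in both TSA libraries), so genes with such a value are given per library. Families of near-identical genes (KRTAP19, MAGE, GAGE, SSX, PAGE, RFPL4, HSPA1) share reads, which makes the values of single members uncertain.

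Each knocked-down gene was lower in its own knockdown. CSE1L (ENSG00000124207) stood at 32.7 ± 3.94 FPKM in siCse1l against 108 ± 3.72 in control B2-1 cells, and at 3.38 ± 0.446 against 32.7 ± 0.312 in HCT116. KPNB1 (ENSG00000108424) stood at 148 ± 14.1 in siKpnb1 against 258 ± 8.94 in control cells, a log2 change of -0.80 ± 0.09 (adjusted p = 7.74e-05) that is smaller than the 1 a call needs. NOVA1 (ENSG00000139910), a neuronal RNA-binding splicing regulator, stood at 1.75 ± 0.621 with siNova1+siHdac1/2 against 7.21 ± 0.762 with siHdac1/2. HDAC1 (ENSG00000116478) and HDAC2 (ENSG00000196591) stood at 19.3 ± 0.531 and 8.93 ± 2.00 with siHdac1/2. No control of that deposit comes from B2-1 cells. Side by side, the controls of the first deposit held 153 ± 0.478 and 141 ± 3.56, a contrast that was not tested across deposits. In the other B2-1 groups of the first deposit CSE1L stood at 81.1 ± 8.27 with siKpnb1, 109 ± 4.12 with 5-Aza, 76.2 ± 0.125 with TSA and 39.2 ± 0.0766 with SAHA. Of the list of 6 perturbation targets (these 5 and DNMT1), 1 was called with siCse1l in B2-1, CSE1L itself. The set test of the whole list gave adjusted p = 0.0146, and adjusted p = 0.350 with an estimated correlation. As CSE1L is a member, part of that shift follows from the knockdown itself. The list's median with TSA, -0.22 as deposited, was 0.19 after quantile normalization and 0.09 after rescaling without mitochondrial transcripts.

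**Figure D1:**
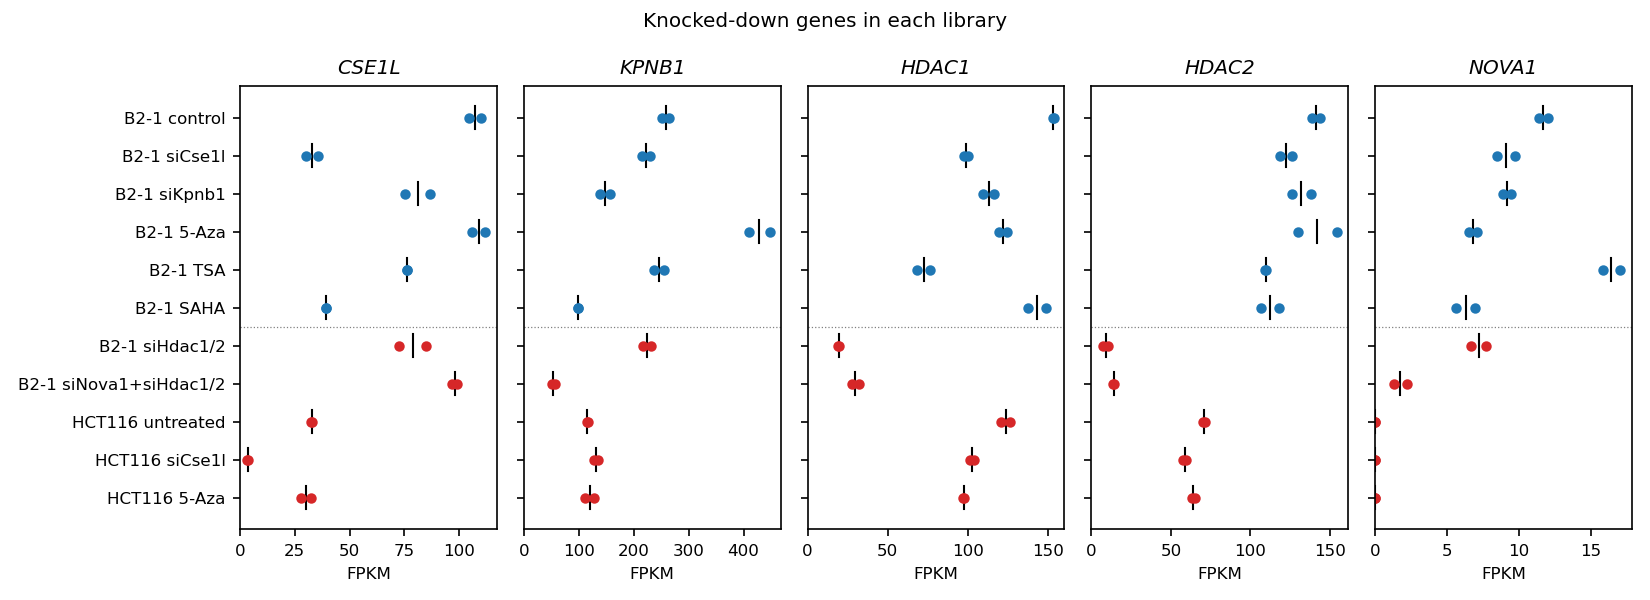
FPKM of the 5 knocked-down genes in each library (points) with the mean of each group (black line); the groups above the dotted line are from the first deposit and those under it from the second. CSE1L was lowest in HCT116 siCse1l, at a mean of 3.38, and KPNB1 was lower with siNova1+siHdac1/2 than with siKpnb1.

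Knocking down CSE1L in B2-1 cells raised 18 of 34 p53 targets, 20 of 30 immediate early genes and 10 of 46 neuronal genes. With an estimated correlation between genes the adjusted p of the 3 lists was 0.00307, 0.0622 and 0.107. Of 13374 genes tested, 539 were called, 315 higher and 224 lower. CDKN1A, the p53-induced inhibitor of cell cycle kinases, rose from 17.5 ± 1.79 to 161 ± 11.1 FPKM (log2 change 3.13 ± 0.09, adjusted p = 1.10e-10). The stress gene GADD45B rose from 4.98 ± 0.334 to 75.2 ± 11.8 (3.67 ± 0.13, adjusted p = 3.97e-10), and FOSB, a subunit of the AP-1 transcription factor, from 0.532 ± 0.0443 to 19.4 ± 4.45 (3.71 ± 0.16, adjusted p = 4.75e-09). CGA, the common alpha subunit of the glycoprotein hormones, rose from 2.02 ± 0.144 to 108 ± 18.9 (5.16 ± 0.13, adjusted p = 1.89e-11). Other large rises were those of the hair keratin-associated gene KRTAP19-1, at 214 and 239.9 against 0.435 and 0.533 FPKM in the single libraries, the lipid phosphatase gene INPP5D (4.19 ± 0.16), the synaptic gene ARC (3.44 ± 0.18) and the heme oxygenase gene HMOX1 (3.11 ± 0.14). Among the falls were HILPDA (-2.17 ± 0.10) and ANKRD37 (-1.79 ± 0.15), which are induced by low oxygen, DDIT4 (-1.59 ± 0.13), an inhibitor of mTORC1, CYB5D2 (-1.86 ± 0.11), and MTG1 (-1.60 ± 0.11), a mitochondrial GTPase.

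By gene list, 18 of 34 p53 targets tested were higher with siCse1l in B2-1 cells and 0 lower (list median 1.08 against -0.10 over all genes; adjusted p = 2.15e-18, and adjusted p = 0.00307 with an estimated correlation). They included PLK2 (3.03 ± 0.18), AEN (2.66 ± 0.09) and GADD45A (2.39 ± 0.10). Of 30 immediate early genes, 20 were higher (median 1.19; adjusted p = 1.79e-19, and adjusted p = 0.0622 with an estimated correlation), among them ATF3 (2.94 ± 0.10) and EGR1 (2.63 ± 0.14). Neuronal genes were higher in 10 of 46 (median 0.58; adjusted p = 3.66e-09, and adjusted p = 0.107 with an estimated correlation), among them the neurofilament genes NEFM (2.24 ± 0.10) and NEFH (at 3.75 and 4.70 against 0.0743 and 0.0455 FPKM), the tubulin gene TUBB3 (2.46 ± 0.16) and the secretory granule gene CHGA (2.80 ± 0.19). Of 23 imprinted genes 4 were higher and 0 lower (adjusted p = 0.0719): the growth regulators PHLDA2 (2.26 ± 0.17), CDKN1C (2.09 ± 0.16) and IGF2 (1.06 ± 0.14), and the retrotransposon-derived PEG10 (1.03 ± 0.16). IGF2 and PEG10 were near the minimum change and fell under it without siCse1l replicate 2 (0.93 for each), PEG10 also without control replicate 1 (0.92) and after quantile normalization (0.93). Heat shock genes (1 of 22 higher; adjusted p = 2.60e-06, and adjusted p = 0.162 with an estimated correlation), metallothioneins (1 of 5; adjusted p = 0.00242, and adjusted p = 0.0834 with an estimated correlation) and cholesterol synthesis genes (0 of 24; adjusted p = 0.0190, and adjusted p = 0.548 with an estimated correlation) also passed the set test. So did the blood list (3 of 5; adjusted p = 0.0113), which had too few members with a value in every library for the test with an estimated correlation. Of the genes listed for siCse1l only 2 were at or under 0.1 FPKM in both of its libraries. Members that stayed silent were thus mostly not tested, which favours rises. Of neuronal genes 46 were tested here and 58 with siKpnb1, and of 17 blood genes found in the files only 5 were tested here.

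With siCse1l in B2-1 cells few members of the silencing and transport machinery were called. At any size of change, adjusted p was under 0.05 for 17 of 38 HDAC and corepressor genes, 12 of 21 DNA methylation genes and 26 of 43 nuclear transport genes. Over all genes it was so for 6101 of 13374. None of these lists passed the set test (adjusted p = 0.972, 0.875 and 0.203). None of the HDAC and corepressor genes was called by limma, although 20 had an unadjusted p under 0.05. The same held for S phase (35 genes, 20 with such a p), G2/M phase (38 and 17), autosomal germline (10 and 8), colon (10 and 4) and embryonic kidney genes (19 and 10). None of the 6 X-linked cancer-testis genes was called, with 6 at an unadjusted p under 0.05 (adjusted p = 0.00778, and adjusted p = 0.20 with an estimated correlation). DNA methylation genes gave 2 higher and 1 lower of 21, interferon-stimulated genes 1 and 3 of 30 (the antiviral gene SAMD9 (-1.37 ± 0.13) fell), and nuclear transport genes 1 and 1 of 43, which were the importin alpha gene KPNA4 (1.32 ± 0.11) and CSE1L itself. Genes reported hypermethylated in colorectal cancer gave 2 higher of 42, histone genes 1 of 20, fibroblast genes 1 of 6, ribosomal protein genes 1 of 63, and stress response genes of the unfolded protein response 3 higher and 1 lower of 38. The balance of directions rested on the scaling and on the minimum change. Quantile normalization gave 353 higher and 144 lower, and median ratio scaling 383 and 129. Without a minimum change it was the reverse, 2334 higher and 3767 lower. The median over all genes, -0.10 as deposited, was 0.001 after median ratio scaling.

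Adjusted over the list alone, the counts of called members were the same as over all genes tested, in each of the 240 pairs of list and comparison. Of 239 pairs with enough members for the set test, 106 had an adjusted p under 0.05 with the preset correlation between genes, and 7 kept it with an estimated correlation. Those were p53 targets in siCse1l against control, siKpnb1 against control and siCse1l against siKpnb1 in B2-1, and immediate early and S phase genes in both HCT116 comparisons. In the first deposit, genes silent in both control and SAHA libraries have no control value and were not tested against control. Tests of lists with many silent members are therefore biased towards rises. With SAHA 15 of 48 cancer-testis and 16 of 49 autosomal germline genes found in the files were tested.

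**Figure D2:**
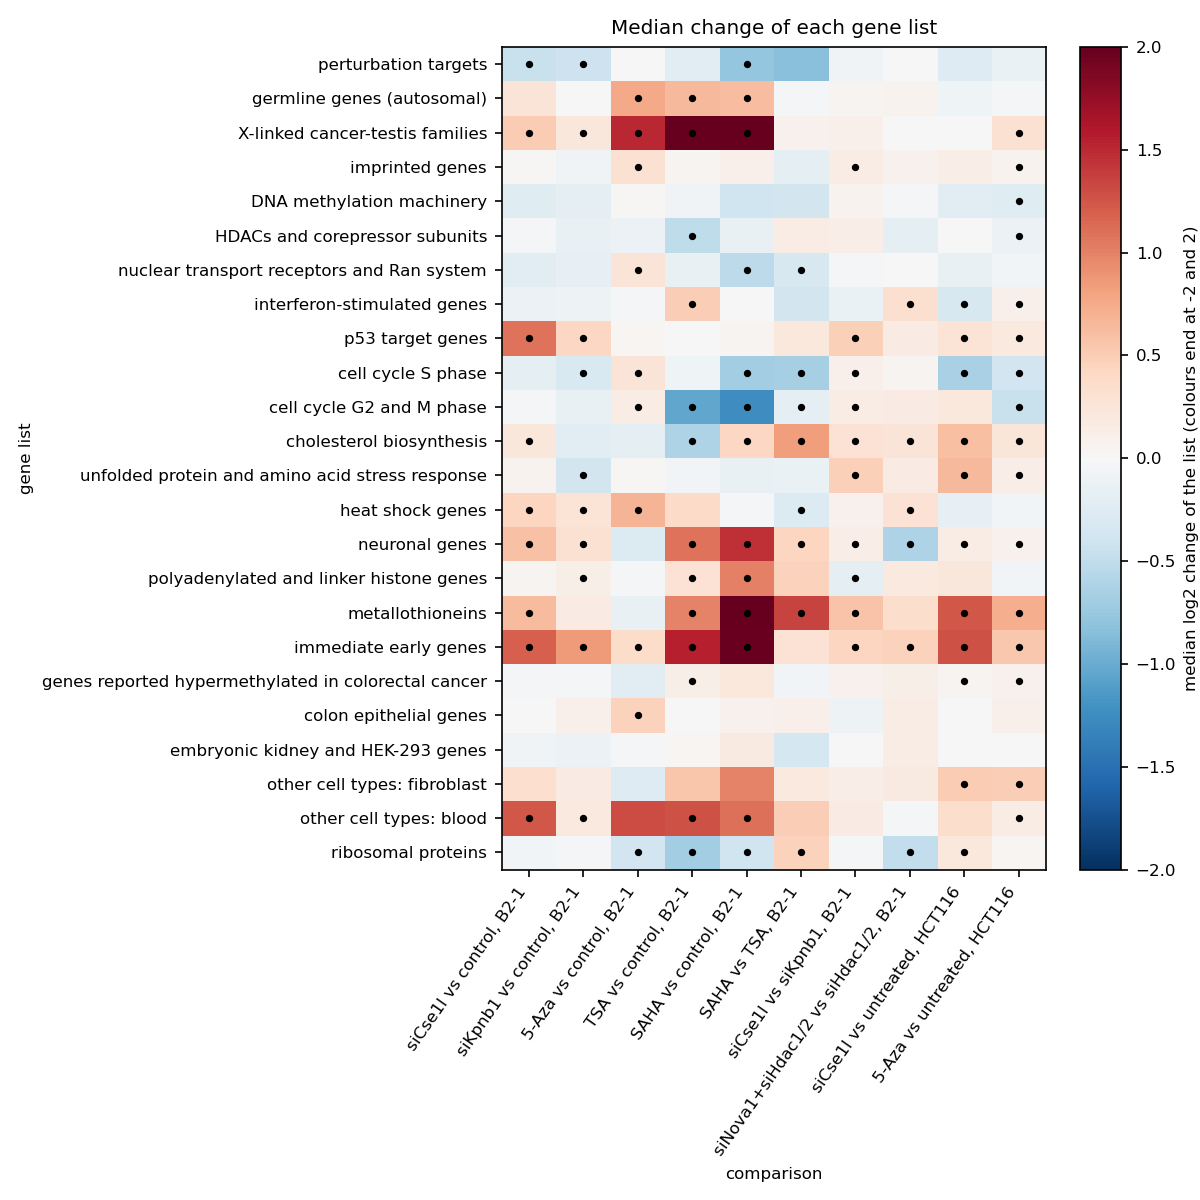
Median log2 change of each gene list (lines) in each comparison (columns), as colour; a black dot marks an adjusted p under 0.05 in the set test with the preset correlation. P53 targets had their highest median, 1.08, with siCse1l in B2-1, and cancer-testis genes theirs with TSA (2.14) and SAHA (2.27). Members silent in both the control and the SAHA libraries of B2-1 cells were not tested against control, which favours rises.

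Knocking down KPNB1, the other transport receptor, called 191 of 14064 genes against control, 132 higher and 59 lower, or 179 and 104 without siKpnb1 replicate 2. The genes raised were largely of the kinds raised with siCse1l: CDKN1A (2.14 ± 0.09, adjusted p = 1.50e-08), GADD45B (2.30 ± 0.13, adjusted p = 1.17e-07), FOSB (2.45 ± 0.16, adjusted p = 7.86e-07), ARC (2.68 ± 0.18), CGA (3.79 ± 0.13), ATF3 (2.33 ± 0.10), JUNB (2.22 ± 0.15), an AP-1 subunit, and DHRS2 (2.60 ± 0.18), a mitochondrial reductase. KRTAP19-1 stood at 27.0 and 20.9 against 0.435 and 0.533 FPKM. The falls included genes induced by low oxygen, DDIT4 (-2.61 ± 0.13, adjusted p = 2.73e-08), HILPDA (-2.26 ± 0.10, adjusted p = 1.50e-08), STC1 (-2.05 ± 0.12), which encodes the hormone stanniocalcin, ANKRD37 (-2.04 ± 0.15), PLOD2 (-1.90 ± 0.14) and LOX (-1.86 ± 0.17), both modifiers of collagen. The neuritin gene NRN1 (-1.86 ± 0.08) fell as well. Of 34 p53 targets 9 were higher (median 0.41 against -0.08 over all genes; adjusted p = 1.75e-10, and adjusted p = 0.0142 with an estimated correlation), among them PLK2 (2.24 ± 0.18), AEN (1.82 ± 0.09) and GADD45A (1.66 ± 0.10). Of 30 immediate early genes 11 were higher and 1 lower (adjusted p = 1.02e-18, and adjusted p = 0.0661 with an estimated correlation). Of 58 neuronal genes 7 were higher (adjusted p = 1.75e-10, and adjusted p = 0.138 with an estimated correlation), along with 2 of 7 blood genes (adjusted p = 0.0304). Among the neuronal ones were TUBB3 (2.13 ± 0.16), NEFM (1.48 ± 0.10) and the neurosecretory gene VGF (1.84 ± 0.20). Genes of the unfolded protein and amino acid stress response went the other way, with 9 of 38 lower and 2 higher (median -0.37; adjusted p = 0.00812, and adjusted p = 0.391 with an estimated correlation). Among them were the asparagine synthetase gene ASNS (-1.76 ± 0.10) and CHAC1 (-1.47 ± 0.11), whose product degrades glutathione. S phase genes had a median of -0.30 with no member called by limma and 21 of 35 at an unadjusted p under 0.05 (adjusted p = 0.00309, and adjusted p = 0.327 with an estimated correlation). With median ratio scaling the calls split into 167 higher and 42 lower, and without a minimum change into 1468 higher and 2547 lower. As KPNB1 itself fell by less than a call needs, the comparison shows a partial knockdown.

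Set against each other, the siCse1l and siKpnb1 responses overlapped, most of all in the rises with siKpnb1. Of 315 rises with siCse1l and 130 with siKpnb1 among genes tested in both, 105 were shared, where independent calls would share 3.10. Of 224 and 59 falls 24 were shared, where independent calls would share 1.00. Across 13374 genes the changes correlated (Pearson r = 0.750, Spearman rho = 0.701), although genes are not independent replicates. Both changes use the same control libraries, which alone gave r = 0.499 in simulated values with no effect. With 1 control library for each, r was 0.647 and 0.699 in the 2 ways to divide them. The covariance was 0.137 against 0.00930 simulated, so the spread between the 2 control libraries accounts for a small part of it. A real difference of the control cells from both is not covered by this or the other simulations. In the direct test siCse1l minus siKpnb1 called 99 of 13403 genes, 80 higher and 19 lower. The split was 76 and 41 without siCse1l replicate 2, 90 and 30 without siKpnb1 replicate 1, and 85 and 30 without siKpnb1 replicate 2. With a pseudocount of 0.1 it was 160 and 113. Higher with siCse1l were the Hippo pathway target ANKRD1 (2.42 ± 0.15), INPP5D (2.38 ± 0.16), and SAT1 (2.23 ± 0.14), which acetylates spermidine. KRTAP19-1 and RFPL4B were higher too, at 214 and 239.9 against 27.0 and 20.9 and 4.41 and 5.31 against 0.499 and 0.294 FPKM. CSE1L (-1.29 ± 0.10), AHNAK2 (-1.35 ± 0.16) and PSKH1 (-1.13 ± 0.10) were lower, and KPNB1 did not pass (0.59 ± 0.09, adjusted p = 0.000958). P53 targets were higher with siCse1l than with siKpnb1 as a list (3 of 34 called, median 0.48 against -0.001 over all genes; adjusted p = 4.09e-13, and adjusted p = 0.00851 with an estimated correlation). The DNA repair gene DDB2 (1.26 ± 0.10) was 1 of them. So were stress response genes (5 of 38; adjusted p = 4.09e-13, and adjusted p = 0.0849 with an estimated correlation) such as ASNS (1.30 ± 0.10) and CHAC1 (1.20 ± 0.11). Cholesterol synthesis genes were higher too (3 of 24; adjusted p = 3.45e-06, and adjusted p = 0.311 with an estimated correlation) with MSMO1 (1.27 ± 0.11) and INSIG1 (1.24 ± 0.14). Immediate early genes followed (4 of 30; adjusted p = 3.62e-08, and adjusted p = 0.230 with an estimated correlation).

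5-Aza in B2-1 cells, which tests what opens when DNA methylation is blocked, raised some germline, cancer-testis and imprinted genes. Of 12950 genes 1345 were called, 322 higher and 1023 lower. With quantile normalization the balance was 373 higher and 384 lower, and with median ratio scaling 511 and 682. The median over all genes was -0.12 as deposited and 0.03 after median ratio scaling. Among the largest rises were ZCCHC12 (4.55 ± 0.14, adjusted p = 1.53e-10), a zinc finger gene, ACRC (4.47 ± 0.14, adjusted p = 1.53e-10), a germ cell nuclear protein gene, PEG10 (4.35 ± 0.16, adjusted p = 8.07e-10) and GTSF1 (4.13 ± 0.14, adjusted p = 1.81e-09), a factor of the germline small RNA pathway. The maternal-effect gene NLRP2 stood at 7.75 and 7.74 against a listed 0 in both FPKM and the cancer-testis gene SSX1 at 7.82 and 6.63 against a listed 0 in both. Of 10 cancer-testis genes 7 were higher and 0 lower (median 1.51; adjusted p = 1.45e-06, and adjusted p = 0.315 with an estimated correlation), among them MAGEB2 (2.75 ± 0.14). Of 48 such genes found in the files only these 10 were tested. No gene listed for 5-Aza was at or under 0.1 FPKM in both of its libraries. Members that stayed silent were thus not tested, which favours rises in this list and in the germline list. Of 14 autosomal germline genes 5 were higher (adjusted p = 0.00125, and adjusted p = 0.338 with an estimated correlation), among them CTCFL (1.61 ± 0.13), SOHLH2 (1.30 ± 0.14) and TDRD12 (1.30 ± 0.15). Imprinted genes gave 4 higher and 2 lower of 22 (adjusted p = 0.0220, and adjusted p = 0.315 with an estimated correlation). PHLDA2 (1.92 ± 0.17), MEST (2.57 ± 0.23) and NNAT (1.93 ± 0.18) rose. GSTP1 (2.01 ± 0.13), whose promoter is a known target of methylation in cancer, rose too.

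Other classes also moved with 5-Aza in B2-1 cells. Immediate early genes gave 9 higher and 1 lower of 29 (adjusted p = 4.17e-05, and adjusted p = 0.315 with an estimated correlation; FOS (2.91 ± 0.15)). Heat shock genes gave 4 higher of 20 (adjusted p = 7.85e-06, and adjusted p = 0.315 with an estimated correlation; HSPH1 (1.72 ± 0.10) and HSPA8 (1.26 ± 0.10)). Nuclear transport genes gave 2 higher of 43 (adjusted p = 0.000157, and adjusted p = 0.322 with an estimated correlation) and S phase genes 1 of 35 (adjusted p = 0.00105, and adjusted p = 0.315 with an estimated correlation). The falls included the BMP inhibitor gene NOG (-2.85 ± 0.13, adjusted p = 1.13e-08), NRN1 (-2.70 ± 0.08, adjusted p = 1.53e-10), LOX (-2.63 ± 0.17), STC1 (-2.53 ± 0.12), ANKRD37 (-2.63 ± 0.15), the trafficking gene RAB26 (-2.47 ± 0.14), the kinase gene BRSK2 (-2.43 ± 0.12) and HLA-DPB1 (-2.43 ± 0.17). Genes reported hypermethylated in colorectal cancer were mostly lower when called, 13 of 42 against 3 higher (adjusted p = 0.529), among them SFRP1 (-1.37 ± 0.10), IGFBP7 (-1.88 ± 0.14) and RASSF2 (-1.51 ± 0.12). Over all genes 1023 of 1345 called were lower, so the balance of this list was near that of the comparison. Neuronal genes split into 8 higher, among them TUBB3 (3.19 ± 0.16), and 5 lower, among them MAPT (-1.92 ± 0.09). Blood genes were higher in 3 of 4 (median 1.31), too few for a set test. The linker histone gene H1F0 (-1.74 ± 0.09), the tubulin deacetylase gene HDAC6 (-1.83 ± 0.13) and RPS10 (-2.0 ± 0.10) fell. The ribosomal protein list had a median of -0.38 and 2 of 63 called (adjusted p = 0.00125, and adjusted p = 0.734 with an estimated correlation). The medians of the neuronal and fibroblast lists were -0.28 and -0.26 as deposited and had the opposite sign, 0.13 and 0.19, after quantile normalization.

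The HDAC inhibitor TSA called 2262 of 14064 genes, 1151 higher and 1111 lower, or 719 and 1070 with the filter at 5. Mitochondrially encoded transcripts took 21.6 and 20.2% of the total in the TSA libraries, against 11.7 and 12.9% in the control libraries. The median over all genes was -0.07 as deposited and 0.20 after rescaling without mitochondrial transcripts, with which the split was 1798 higher and 494 lower. It was 1385 and 730 with median ratio scaling. CGA (7.46 ± 0.13, adjusted p = 2.73e-13) and the neurosecretory gene VGF (6.17 ± 0.20, adjusted p = 4.94e-11) rose, as did ARC (6.12 ± 0.18, adjusted p = 1.46e-11), GADD45B (5.67 ± 0.13, adjusted p = 1.21e-12), the neuropeptide gene NTS (5.76 ± 0.13), ANKRD1 (7.20 ± 0.15) and CTGF (5.28 ± 0.15), a matrix-associated growth factor gene. HDAC1 was just past the minimum change (-1.07 ± 0.08, adjusted p = 1.60e-07) and under it without TSA replicate 1 (-0.999), after quantile normalization (-0.71), after median ratio scaling (-0.92) and after rescaling without mitochondrial transcripts (-0.77). Falls included NRN1 (-3.22 ± 0.08, adjusted p = 5.01e-12), the glucocorticoid-induced TSC22D3 (-3.17 ± 0.14, adjusted p = 1.09e-09), the GTPase gene RAC3 (-3.01 ± 0.12), the spindle gene PSRC1 (-2.83 ± 0.13) and E2F5 (-2.71 ± 0.14), which encodes a cell cycle transcription factor. Of 58 neuronal genes 34 were higher and 1 lower (median 1.08; adjusted p = 1.66e-11, and adjusted p = 0.108 with an estimated correlation), among them NEFM (4.39 ± 0.10) and CHGA (4.89 ± 0.19). Markers of other cell types rose too, blood genes in 4 of 7 (adjusted p = 0.0312) and fibroblast genes in 2 of 9 (adjusted p = 0.0534). Cancer-testis genes were higher in 10 of 15 (adjusted p = 2.82e-07, and adjusted p = 0.198 with an estimated correlation), with MAGEB2 (4.13 ± 0.14) and MAGEC2 at 32.2 and 28.5 against 0.0565 and 0.0288 FPKM. Germline genes were higher in 5 of 16 (adjusted p = 0.0340, and adjusted p = 0.520 with an estimated correlation), among them TEX19 (4.25 ± 0.12). Immediate early genes were higher in 21 of 30 (adjusted p = 5.24e-14, and adjusted p = 0.108 with an estimated correlation), such as EGR1 (5.20 ± 0.14). G2/M genes were lower in 22 of 38 (median -1.04; adjusted p = 5.26e-12, and adjusted p = 0.108 with an estimated correlation), among them TOP2A (-1.75 ± 0.08), KIF20A (-1.72 ± 0.09) and CCNB2 (-1.69 ± 0.09). Ribosomal protein genes were lower in 18 of 63 and higher in 1 (median -0.70; adjusted p = 2.10e-10, and adjusted p = 0.477 with an estimated correlation), among them RPLP0 (-1.45 ± 0.10) and RPSA (-1.35 ± 0.10). These 2 were under the minimum change after quantile normalization (-0.92 and -0.96). HDAC and corepressor genes gave 6 lower of 38 (adjusted p = 0.0312, and adjusted p = 0.477 with an estimated correlation).

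SAHA called 3322 of 14064 genes, 1759 higher and 1563 lower, or 2271 and 1092 after rescaling without mitochondrial transcripts, which moved the median over all genes from -0.02 to 0.16. With the filter at 5 the split was 1115 and 1455. Both transport receptors of the knockdowns were lower: CSE1L (-1.43 ± 0.10, adjusted p = 2.44e-08) and KPNB1 (-1.39 ± 0.09, adjusted p = 1.73e-08). The largest rises included CGA (9.32 ± 0.13, adjusted p = 1.38e-14), ANKRD1 (8.05 ± 0.15, adjusted p = 1.32e-13), NTS (8.04 ± 0.13, adjusted p = 2.87e-14), CTGF (6.43 ± 0.15), VGF (6.06 ± 0.20), DHRS2 (5.89 ± 0.18) and GPR50 (5.34 ± 0.14), which encodes an orphan receptor. The largest falls included the mitochondrial kinase gene NME4 (-4.04 ± 0.11, adjusted p = 7.25e-12), the apoptosis genes BID (-3.79 ± 0.13, adjusted p = 5.18e-11) and FAIM (-3.44 ± 0.13), the insulin receptor substrate gene IRS4 (-3.75 ± 0.20), the histone variant gene H2AFY2 (-3.42 ± 0.12) and ANP32B (-3.28 ± 0.09). Neuronal genes were higher in 35 of 58 (median 1.46; adjusted p = 2.34e-13, and adjusted p = 0.0946 with an estimated correlation; NEFM (4.29 ± 0.10)). So were blood genes in 4 of 7 (adjusted p = 0.00357) and fibroblast genes in 4 of 9 (adjusted p = 0.0819). Cancer-testis genes were higher in 11 of 15 (adjusted p = 1.47e-05, and adjusted p = 0.356 with an estimated correlation; MAGEB2 (4.61 ± 0.14)), and immediate early genes in 24 of 30 (adjusted p = 1.12e-10, and adjusted p = 0.0946 with an estimated correlation). All 5 metallothioneins tested were higher (adjusted p = 0.00104, and adjusted p = 0.0946 with an estimated correlation), such as MT2A (2.44 ± 0.13) and MT1X (3.06 ± 0.20). Histone genes gave 11 higher and 2 lower of 20 (adjusted p = 0.00825, and adjusted p = 0.365 with an estimated correlation), with H1F0 (1.91 ± 0.09). G2/M genes were lower in 26 of 38 (median -1.24; adjusted p = 1.81e-12, and adjusted p = 0.0946 with an estimated correlation; PLK1 (-2.19 ± 0.10) and TOP2A (-1.84 ± 0.08)). S phase genes were lower in 13 of 35 (adjusted p = 1.81e-05, and adjusted p = 0.272 with an estimated correlation; TYMS (-2.55 ± 0.08)). Of 43 nuclear transport genes 10 were lower and 1 higher (adjusted p = 0.00180, and adjusted p = 0.510 with an estimated correlation), among them RAN (-2.53 ± 0.09), the GTPase that drives transport. Cholesterol synthesis genes were higher in 6 of 24 (adjusted p = 0.0205, and adjusted p = 0.510 with an estimated correlation; HMGCS1 (2.40 ± 0.14)).

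TSA and SAHA shared 779 called genes higher (144 with independent calls) and 544 lower (124), with 6 called in opposite directions. Across genes r was 0.723 and the covariance 0.544, against 0.499 and 0.00950 simulated from shared controls. A direct test called 1691 genes, 843 higher and 848 lower with SAHA, or 647 and 1085 after rescaling without mitochondrial transcripts. The 95% interval of the difference lay within 1 of 0 on the log2 scale for 10313 of 14064 genes, for 557 of the 779 higher with both inhibitors and for 442 of the 544 lower with both. Higher with SAHA were SLC2A3 (3.21 ± 0.14, adjusted p = 2.62e-09), a glucose transporter gene, ALDOA (2.44 ± 0.11), which encodes an aldolase, and the hypoxia-induced ANKRD37 (2.77 ± 0.15). Cholesterol synthesis genes were higher in 11 of 24 (median 0.84 against 0.08 over all genes; adjusted p = 1.40e-06, and adjusted p = 0.319 with an estimated correlation). Part of this was a fall with TSA, which against control lowered 4 of 24 and raised 0 (median -0.61, adjusted p = 0.0340, and adjusted p = 0.520 with an estimated correlation). SAHA raised 6 of 24 and lowered 0 (median 0.42). Metallothioneins were higher in 3 of 5 (adjusted p = 0.00807, and adjusted p = 0.216 with an estimated correlation; MT2A (1.46 ± 0.13)). Neuronal genes were higher in 12 of 58 (adjusted p = 0.00386, and adjusted p = 0.486 with an estimated correlation; RAB3A (2.19 ± 0.16)). HDAC3 (1.33 ± 0.08) and H1F0 (2.04 ± 0.09) were higher too. Lower with SAHA were FJX1 (-3.11 ± 0.11, adjusted p = 4.66e-10), the aryl hydrocarbon receptor repressor gene AHRR (-2.90 ± 0.11), FAIM (-2.88 ± 0.13), ANP32B (-2.72 ± 0.09), KPNB1 (-1.32 ± 0.09) and NOVA1 (-1.26 ± 0.12). So were 9 of 35 S phase genes (adjusted p = 1.04e-09, and adjusted p = 0.216 with an estimated correlation) and 5 of 43 nuclear transport genes (adjusted p = 0.000102, and adjusted p = 0.453 with an estimated correlation). CSE1L and HDAC1 did not pass (differences and intervals -0.94, -1.15 to -0.73 and 0.97, 0.79 to 1.16). CSE1L passed after quantile normalization (-1.10) and after rescaling without mitochondrial transcripts (-1.05), and HDAC1 without SAHA replicate 1 (1.03) or TSA replicate 2 (1.05). Cancer-testis genes differed in 1 of 15 (adjusted p = 0.726).

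Overlaps between CSE1L knockdown and the drugs ran higher in genes that rose than in genes that fell. The siCse1l and SAHA calls in B2-1 shared 206 genes higher (31.5 with independent calls) and 73 lower (26.2), with r = 0.491 across genes. For TSA these were 165 (19.6), 37 (18.6) and r = 0.377, and for 5-Aza 74 (6.20), 44 (17.7) and r = 0.271. All 3 pairs use the same 2 control libraries. With 1 library for each comparison of a pair, divided in both ways after the results were seen, siCse1l shared at least 211 rises with SAHA (33.3 with independent calls), 162 with TSA (21.2) and 71 with 5-Aza (6.40). It shared at least 68 (29.1), 36 (20.6) and 48 falls (18.2), and r was at least 0.460, 0.340 and 0.228, so noise in a shared library does not account for the overlaps. A difference of the control cells held by both libraries would remain. The covariances were 0.222, 0.142 and 0.0796, against 0.00930, 0.00930 and 0.00910 simulated. The shared controls alone gave r = 0.499, 0.499 and 0.498 in simulated values with no effect, so r with both control libraries does not by itself show an overlap. Genes silent in control enter only if SAHA libraries express them, which adds to overlaps of rises. Among genes at or over 1 in both control libraries, a set chosen after the result was seen, siCse1l shared 133 rises with SAHA (16.9 with independent calls), 102 with TSA (9.60) and 43 with 5-Aza (3.70). CSE1L itself was low with SAHA (39.2 FPKM, against 32.7 with siCse1l and 108 in control), less so with TSA (76.2) and not with 5-Aza (109). HDAC1 stood at 98.8 with siCse1l against 153 in control, a fall that was not called. What part of the overlaps follows from these was not tested.

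**Figure D3:**
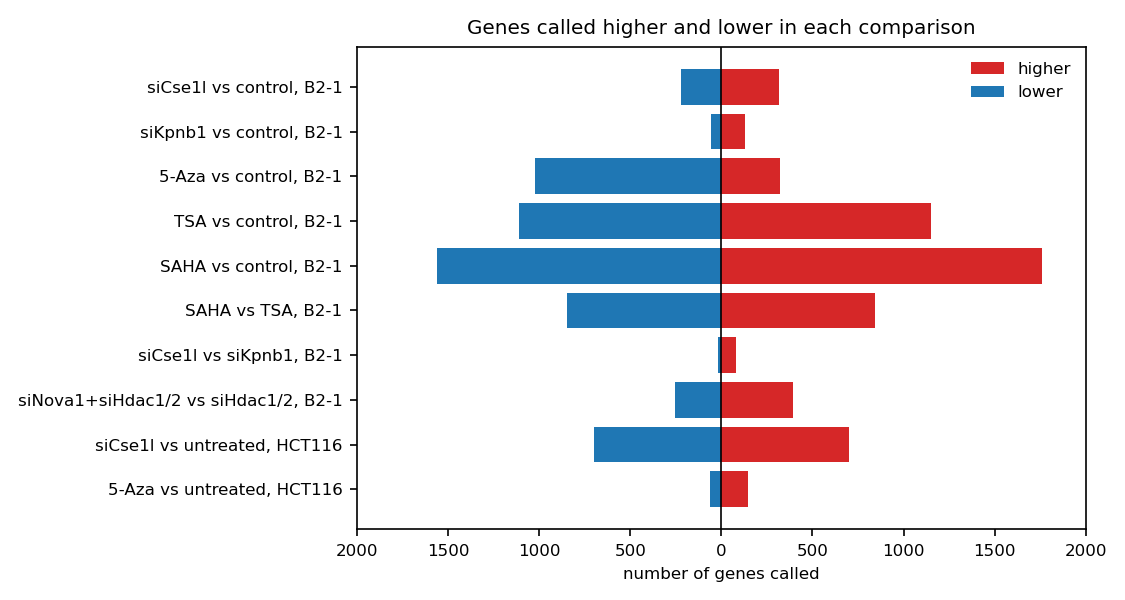
Number of genes called higher (red, to the right) and lower (blue, to the left) in each comparison. SAHA had the most, 1759 higher and 1563 lower, and siCse1l against siKpnb1 the fewest, 80 and 19.

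Genes that went from silent to transcribed were counted as those at or under 0.1 FPKM in both control libraries and at or over 1 in both treated ones. With SAHA 204 genes did so and 5 did the reverse, and with TSA 142 and 3. 5-Aza turned on 18 and siKpnb1 4, with 0 and 1 in reverse. CSE1L knockdown in B2-1 turned on 9 genes and turned off 0. They were KRTAP19-3, TEX37, RFPL4B, NEFH, USP17L2, RFPL4A, CYP4F2, ACTBL2 and MUC19, named after the values were seen. These counts are limits of what the files list: each of the 482 genes silent in control reached 0.5 in a SAHA library, so genes silent in both have no control value, and the number shared between treatments is not given. Only 31 of the 482 are listed for siCse1l and 41 for 5-Aza. Conversely, 126 genes at or over 1 in both control libraries are not listed for 5-Aza, and 5 for siCse1l, so a fall to near 0 can be missing there. The listing also caps the reverse counts. Of the genes listed, only 8 were at or under 0.1 in both SAHA libraries, 2 in both siCse1l libraries and 0 in both 5-Aza libraries. For TSA and siKpnb1 only genes listed for SAHA have a control value. The balance of genes turned on and off in these B2-1 comparisons was therefore not measured evenly. In the second deposit, whose files list nearly the same genes, knocking down CSE1L in HCT116 turned on 24 and turned off 8, 5-Aza in HCT116 10 and 4, and adding siNova1 to siHdac1/2 11 and 8. For CSE1L knockdown the count ran over 58750 genes in HCT116 and over 13517 in B2-1, so the numbers of the 2 lines cannot be compared. With limits of 0.5 and 2 the balance for CSE1L knockdown in HCT116 was the reverse, 22 on and 35 off. For siNova1 it was 8 and 9, and for 5-Aza in B2-1 24 and 11.

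Adding siNova1 to siHdac1/2 in B2-1 cells lowered some neuronal genes. Of 17644 genes 649 were called, 394 higher and 255 lower, or 485 and 200 after rescaling without mitochondrial transcripts. NOVA1 fell (-1.60 ± 0.16, adjusted p = 0.000184), and so did KPNB1, from 224 ± 10.7 to 53.8 ± 4.0 FPKM (-2.04 ± 0.08, adjusted p = 4.94e-06). The falls included those of SYP (-3.77 ± 0.13, adjusted p = 2.56e-06), CHGB (-2.90 ± 0.14, adjusted p = 8.67e-06), CHGA (-2.74 ± 0.19, adjusted p = 3.56e-05), SCAMP5 (-2.64 ± 0.15) and SNAP25 (-2.07 ± 0.13). They also included the microtubule gene STMN3 (-3.37 ± 0.10), the membrane gene TMEM198 (-3.42 ± 0.13), the vesicle coat gene SEC23A (-2.88 ± 0.16) and PHF21B (-2.67 ± 0.13). Of 55 neuronal genes 18 were lower and 4 higher (median -0.62; adjusted p = 5.16e-06, and adjusted p = 0.270 with an estimated correlation). Among the largest rises were CGA (4.77 ± 0.10, adjusted p = 7.46e-08), the ETS factor gene ETV4 (2.80 ± 0.12, adjusted p = 5.02e-06), CDK2AP1 (2.30 ± 0.11) and ARC (2.23 ± 0.15). Immediate early genes were higher in 7 of 30 (adjusted p = 3.88e-07, and adjusted p = 0.0716 with an estimated correlation), such as FOS (2.05 ± 0.11), EGR1 (1.86 ± 0.10) and JUNB (1.33 ± 0.08). Interferon-stimulated genes were higher in 2 of 34 (adjusted p = 0.00735, and adjusted p = 0.117 with an estimated correlation). Heat shock genes gave 2 of 20 (adjusted p = 0.000754, and adjusted p = 0.117 with an estimated correlation). Imprinted genes higher were 3 of 29 (adjusted p = 0.222), with IGF2 (1.60 ± 0.13) and CDKN1C (1.22 ± 0.13). Genes hypermethylated in colorectal cancer gave 6 higher and 2 lower of 41 (adjusted p = 0.191), with TFPI2 (1.56 ± 0.11) higher. Ribosomal protein genes had a median of -0.49 against 0.01 over all genes, with 1 of 63 called (adjusted p = 4.01e-21, and adjusted p = 0.270 with an estimated correlation).

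In HCT116 cells CSE1L knockdown raised many immediate early genes and lowered some S phase genes. Of 17643 genes 1401 were called, 700 higher and 701 lower. After rescaling without mitochondrial transcripts the split was 497 higher and 1088 lower, with the median over all genes at -0.14 in place of -0.02. Histone genes gave 6 higher and 1 lower of 22 and did not pass as a list (adjusted p = 0.0765). CSE1L fell (-2.95 ± 0.11, adjusted p = 1.19e-06). The largest rises included the arrestin-related gene ARRDC4 (4.49 ± 0.15, adjusted p = 5.86e-07), the histone genes HIST2H2BE (3.33 ± 0.19, adjusted p = 7.13e-06) and HIST1H1C (2.85 ± 0.13) and ATF3 (2.99 ± 0.09, adjusted p = 4.66e-07). They also included DDIT3 (2.83 ± 0.13), a factor of the unfolded protein response, EGR1 (2.83 ± 0.10), the sterol sensor gene INSIG1 (2.82 ± 0.15), and ANGPTL4 (2.79 ± 0.22) and ANKRD37 (2.78 ± 0.17), which are induced by low oxygen. The largest falls included the neurotensin receptor gene NTSR1 (-2.86 ± 0.11, adjusted p = 1.26e-06), ITPRIPL2 (-2.61 ± 0.10, adjusted p = 1.31e-06), NCOA5 (-2.35 ± 0.09) and SAMD9 (-2.23 ± 0.13). Immediate early genes were higher in 20 of 30 (median 1.27; adjusted p = 1.01e-14, and adjusted p = 0.0124 with an estimated correlation), such as NR4A1 (2.35 ± 0.07) and JUN (2.29 ± 0.07). S phase genes were lower in 5 of 35 (median -0.65; adjusted p = 2.02e-07, and adjusted p = 0.0243 with an estimated correlation), such as CHAF1A (-1.08 ± 0.11), which was under the minimum change without siCse1l replicate 2 (-0.94). Genes of the unfolded protein response gave 11 higher and 1 lower of 37 (adjusted p = 3.13e-07, and adjusted p = 0.10 with an estimated correlation), among them the chaperone gene HSPA5 (2.76 ± 0.09). Cholesterol synthesis genes gave 9 higher of 25 (adjusted p = 1.04e-07, and adjusted p = 0.121 with an estimated correlation; MSMO1 (1.95 ± 0.12)). Metallothioneins gave 4 of 6 (adjusted p = 5.80e-05, and adjusted p = 0.10 with an estimated correlation; MT1X (2.46 ± 0.13)). P53 targets were higher in 7 of 33 (adjusted p = 0.000208, and adjusted p = 0.0966 with an estimated correlation), among them SFN (1.59 ± 0.07), PLK3 (2.19 ± 0.08) and BBC3 (1.73 ± 0.09). CDKN1A has no value in these libraries. Imprinted genes were higher in 3 of 29 (adjusted p = 0.0633), with CDKN1C (2.69 ± 0.13). Interferon-stimulated genes were lower in 7 and higher in 2 of 34 (adjusted p = 0.0165, and adjusted p = 0.101 with an estimated correlation). DTX3L (-1.81 ± 0.15) and PARP9 (-1.56 ± 0.12) were lower. Fibroblast genes were higher in 1 of 6 (adjusted p = 0.0211, and adjusted p = 0.121 with an estimated correlation). The ribosomal protein median was 0.21 as deposited and -0.09 after quantile normalization.

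5-Aza in HCT116 cells called 208 of 17645 genes, 145 higher and 63 lower. The split was 124 and 97 after rescaling without mitochondrial transcripts, and 153 and 109 without 5-Aza replicate 2. With the filter at 5 it was 109 and 35. The imprinted noncoding RNA MEG3 stood at 7.25 and 7.93 against 0.0157 and a listed 0 FPKM and the cancer-testis gene MAGEA4 at 4.58 and 5.31 against a listed 0 in both. H19 (2.99 ± 0.21, adjusted p = 0.000176), also imprinted and noncoding, rose, as did ARRDC4 (3.07 ± 0.15, adjusted p = 1.88e-05), the macrophage marker CD68 (2.46 ± 0.26), IGFBP3 (2.42 ± 0.11) and the decoy receptor gene TNFRSF6B (2.33 ± 0.08). The transketolase-like gene TKTL1 stood at 5.19 and 6.95 against a listed 0 and 0.214 FPKM and the ubiquitin hydrolase gene UCHL1 at 3.71 and 4.32 against 0.142 and a listed 0. The falls included the transporter gene ABCC2 (-1.82 ± 0.15, adjusted p = 0.000320), PDE4B (-1.36 ± 0.18, adjusted p = 0.00221) and DCBLD2 (-1.36 ± 0.13). Cancer-testis genes were higher in 2 of 7 (adjusted p = 0.000989, and adjusted p = 0.0809 with an estimated correlation). So were imprinted genes in 2 of 29 (adjusted p = 0.0290, and adjusted p = 0.158 with an estimated correlation) and genes hypermethylated in colorectal cancer in 4 of 41 (adjusted p = 0.00468, and adjusted p = 0.0811 with an estimated correlation), with VIM (1.34 ± 0.16). P53 targets were higher in 4 of 34 (adjusted p = 4.91e-05, and adjusted p = 0.0809 with an estimated correlation; SFN (1.53 ± 0.07)). Immediate early genes were higher in 4 of 30 (adjusted p = 4.98e-12, and adjusted p = 0.0148 with an estimated correlation; EGR1 (1.26 ± 0.10)) and metallothioneins in 2 of 6 (adjusted p = 4.91e-05, and adjusted p = 0.0809 with an estimated correlation; MT2A (1.45 ± 0.09)). Fibroblast and blood genes were higher in 1 of 6 (adjusted p = 0.0152, and adjusted p = 0.106 with an estimated correlation) and 1 of 5 (adjusted p = 0.0225, and adjusted p = 0.122 with an estimated correlation). S phase genes had a median of -0.38 (adjusted p = 4.21e-09, and adjusted p = 0.0148 with an estimated correlation) and G2/M genes of -0.45 (adjusted p = 5.93e-10, and adjusted p = 0.235 with an estimated correlation). None of either list was called by limma, with 24 of 35 and 25 of 38 at an unadjusted p under 0.05. The 2 HCT116 comparisons shared 91 genes higher (5.70 with independent calls) and 48 lower (2.5), with r = 0.667 across genes. The untreated libraries they share gave r = 0.499 in simulated values with no effect. With 1 of them for each comparison r was 0.541 and 0.536. The covariance was 0.133 against 0.0140 simulated.

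The responses to CSE1L knockdown in B2-1 and HCT116, which share no controls, correlated across genes (r = 0.510), with 104 genes called higher in both (10.6 with independent calls), 89 lower in both (8.0) and 6 in opposite directions. Neither control group is labelled as transfected, so a response to transfection can be part of this. Other pairs across lines gave r = 0.314 (siCse1l in B2-1 with 5-Aza in HCT116), 0.259 (siKpnb1 in B2-1 with siCse1l in HCT116) and -0.057 (5-Aza in B2-1 with siCse1l in HCT116). A test of the difference between the lines called 628 of 12945 genes, 297 higher and 331 lower in B2-1. The split was 343 and 254 after quantile normalization, 373 and 268 after median ratio scaling and 547 and 172 after rescaling without mitochondrial transcripts. For 5-Aza the changes in the lines did not go together (r = -0.0430), with 16 genes higher in both (1.90 with independent calls), 0 lower in both (1.70) and 12 in opposite directions. The difference was called for 1825 of 12688 genes, 477 higher and 1348 lower in B2-1, or 568 and 708 after quantile normalization and 731 and 1037 after median ratio scaling. TKTL1 was called higher in both lines, and rose by 1.69 ± 0.12 in B2-1. Line and deposit coincide in each of these tests, so a difference between deposits is part of each difference between lines.

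**Figure D4:**
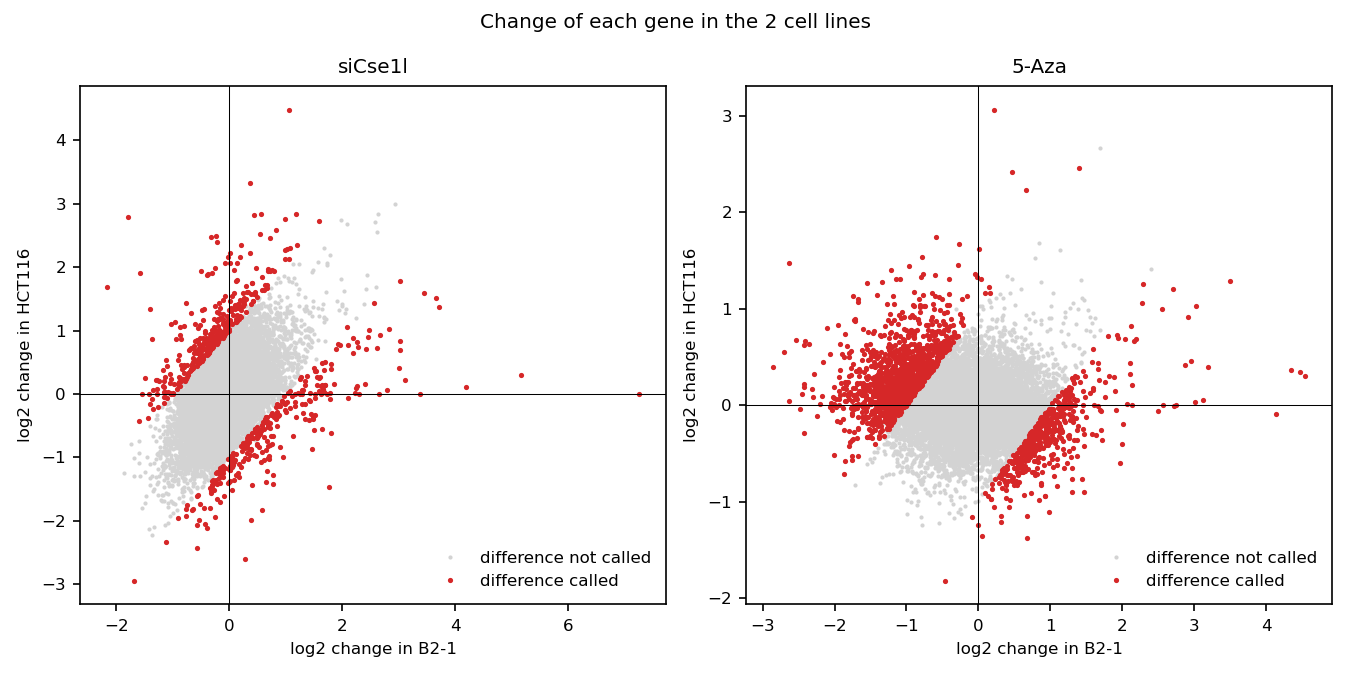
Log2 change of each gene in B2-1 (horizontal) and HCT116 (vertical) for siCse1l and 5-Aza, with genes whose difference between lines was called in red. The siCse1l points follow a common slope (r = 0.51) and the 5-Aza points do not (r = -0.043).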

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

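The list of hypoxia-response genes used here, the test of the control libraries against the siHdac1/2 libraries, and the tests of cell cycle genes and of genes matched on level against the list's interval were chosen after the result was seen. The other tests in this part were fixed before their results were seen.

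Differences between the 2 cell lines are given first, each flagged because a limma test of the difference itself was called. The difference was called for 628 genes with CSE1L knockdown and for 1825 with 5-Aza. For CSE1L knockdown, the change in B2-1 minus that in HCT116 (log2 ± SE) was negative for ANKRD37 (-4.57 ± 0.23), HILPDA (-3.85 ± 0.17) and DDIT4 (-3.50 ± 0.18), which were lower in B2-1 and higher in HCT116, and for ARRDC4 (-3.44 ± 0.18), INSIG1 (-2.39 ± 0.22) and the chaperone gene HSPA5 (-1.77 ± 0.12), which rose by more in HCT116. It was positive for CGA (4.86 ± 0.17), HMOX1 (2.89 ± 0.19), CHGA (2.75 ± 0.28), NEFM (2.14 ± 0.14), PLK2 (2.19 ± 0.26) and AEN (1.74 ± 0.11), and for CSE1L itself (1.26 ± 0.15), whose own fall was larger in HCT116. For 5-Aza it was negative for ANKRD37 (-4.10 ± 0.23), NRN1 (-3.25 ± 0.12), NOG (-3.25 ± 0.18), HDAC6 (-2.07 ± 0.17), IGFBP3 (-1.96 ± 0.14) and UCHL1 (-1.57 ± 0.12), and positive for PEG10 (3.98 ± 0.23), ACRC (4.13 ± 0.18), GTSF1 (4.22 ± 0.18), MEST (2.57 ± 0.29), GSTP1 (2.20 ± 0.20) and HSPH1 (2.08 ± 0.16). With siCse1l, CGA, HMOX1, CHGA and NEFM changed little in HCT116 (0.29, 0.22, 0.05 and 0.10), while PLK2 and AEN rose there by 0.84 and 0.93. A gene hardly transcribed in HCT116 was not told from one that responds differently. The unequal fall of CSE1L can also be part of the siCse1l differences. Line and deposit coincide, so which of them a difference belongs to could not be tested.

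Genes induced by low oxygen were lower than control in 4 of the 5 treated B2-1 groups of the first deposit: list medians were -0.44 with siCse1l (9 of 34 lower), -0.85 with siKpnb1 (16 lower), -0.91 with 5-Aza (16) and -0.70 with TSA (15 lower, 3 higher), and 0.11 with SAHA (8 higher, 3 lower). Unadjusted p with an estimated correlation was 0.139, 0.0112, 0.0448 and 0.237 in the 4, and the same list was higher in HCT116 with siCse1l (median 1.09, 19 of 36 higher, p = 0.101) and 5-Aza (0.56, 7, p = 0.119), and with SAHA against TSA (1.13, 18 of 34, p = 0.0796). With 5-Aza, S and G2/M phase genes showed no fall, with a median of 0.336 (95% interval 0.219 to 0.421, genes resampled as if independent) relative to all genes. Neither list passed with an estimated correlation (adjusted p = 0.315 and 0.514). Transcript levels also do not measure how many cells cycle, so fewer cycling cells stay open there. They also stay open with TSA (-0.561), siKpnb1 (-0.110) and siCse1l (0.029), though SAHA lowered those genes most (-1.05) without the fall. Against random lists matched on level (percentile 0 for siKpnb1, 1st percentile at the lowest -0.273 with siKpnb1 and 5-Aza, -0.521 with siCse1l and TSA) the rank of a list made after its genes were seen to fall decides nothing. The matched genes themselves had a median change of only -0.092 with siKpnb1, -0.021 with 5-Aza and -0.075 with siCse1l. The list's was -0.854, -0.912 and -0.444 (95% interval with siCse1l -0.779 to -0.254, genes resampled as if independent). That argues against a general fall of abundant genes with siKpnb1, 5-Aza and siCse1l. It stays open with TSA (matched median -0.225). The control libraries may also stand apart. The list was higher in them than in the siHdac1/2 B2-1 libraries by 1.04 (95% interval 0.833 to 1.29, genes resampled as if independent) relative to all genes. This decides nothing, because the list was made after its genes were seen to be higher in these control libraries than in treated ones. The siHdac1/2 libraries are also a knockdown from another deposit. An effect common to the treatments was thus not told from one of the control cells.

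KPNB1 fell by 2.04 on the log2 scale when siNova1 was added to siHdac1/2, more than with siKpnb1, and 18 of 55 neuronal genes were called lower and 4 higher (adjusted p = 0.270 with an estimated correlation). The prediction for KPNB1 as the driver was that the changes follow those with siKpnb1, and they did not, with a Spearman correlation of 0.054 across 13165 genes. There were 26 rises called in both (3.0 with independent calls), 0 shared falls and 10 genes called opposite. This cannot decide the question, because the contrasts are unlike. With siKpnb1 the fall of KPNB1 was smaller, HDAC1 and HDAC2 were not targeted, and the control cells are not labelled as transfected. The deposits differ too. A weaker HDAC knockdown with 3 targets stays open: HDAC1 stood at 29.8 ± 2.99 FPKM against 19.3 ± 0.531 and HDAC2 at 13.9 ± 0.587 against 8.93 ± 2.00, and 138 genes were called opposite to SAHA (57.4 with independent calls) and 88 to TSA (39.2), but 59 rises were shared with each (32.6 and 20.4). The median change of 563 genes raised by both inhibitors was 0.088 (95% interval 0.049 to 0.127), but 47 were called higher and 39 lower, so it decides nothing. An effect of losing NOVA1, which acts in neurons, or of the added small interfering RNA on other genes was not tested.

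After 5-Aza in B2-1 23.9% of called genes were higher. With the siKpnb1 or siCse1l libraries as the reference the share was 33% at most, so the imbalance was there with other references too. Those references are knockdowns themselves, and only 650 and 670 of the 1345 calls were made again with them. Control libraries that stand apart therefore stay open as part of the cause. Under quantile normalization the share reached 49.3%, so the scaling between libraries may account for much of the imbalance. A global fall of transcripts after 5-Aza could give the same values, since neither scaling can see it, and was not tested.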

How the results depend on the processing

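Rescaling without mitochondrial transcripts, the siKpnb1 and siCse1l libraries as the reference for 5-Aza, the overlaps among genes at or over 1 in both control libraries, and those with divided control libraries were chosen after the data were seen. The other alternatives were fixed before.

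Counts of called genes stayed within 1.5 times the reported ones in 142 of the alternatives run, among them no filter, a filter at 5, only the 2 groups compared, median ratio scaling, rescaling without mitochondrial transcripts, and every removal of 1 library. With the filter at 5 the totals for TSA and SAHA stayed within that limit but their rises did not (719 in place of 1151 and 1115 in place of 1759), and nor did the falls for 5-Aza in HCT116 (35 in place of 63). Totals moved further in 22. With 1 library left out, the lone library was assumed to vary like the others, and counts ran from 513 to 638 for siCse1l in B2-1, 180 to 283 for siKpnb1 and 1229 to 1520 for 5-Aza. They were 2274 to 2304 for TSA, 3253 to 3373 for SAHA, 1644 to 1800 for SAHA against TSA and 115 to 125 for siCse1l against siKpnb1. They were 611 to 697 for siNova1, 1322 to 1495 for siCse1l in HCT116, 169 to 262 for 5-Aza in HCT116, and 612 to 715 and 1721 to 2012 for the differences between lines with siCse1l and 5-Aza. As the reference for 5-Aza in B2-1, siKpnb1 libraries gave 1099 genes and siCse1l libraries 1581, against 1345 with control. Of the 1345 only 650 and 670 were called again with these references.

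A pseudocount of 0.1 in place of 1, which by its construction enlarges the changes of genes with low values, gave 1090 genes in place of 539 for siCse1l in B2-1, 638 in place of 191 for siKpnb1 and 2190 in place of 1345 for 5-Aza in B2-1. It gave 2558 in place of 1691 for SAHA against TSA, 273 in place of 99 for siCse1l against siKpnb1 and 1288 in place of 649 for siNova1. In HCT116 it gave 2715 in place of 1401 for siCse1l and 596 in place of 208 for 5-Aza. For the difference between lines with siCse1l it gave 1168 in place of 628. Without a minimum change, which admits smaller changes, the counts were 6101, 4015, 7616, 8902, 10024, 8862, 2920, 5821, 7769, 2688, 3852 and 6342 for siCse1l, siKpnb1, 5-Aza, TSA and SAHA in B2-1, SAHA against TSA, siCse1l against siKpnb1, siNova1, siCse1l and 5-Aza in HCT116, and the differences between lines with siCse1l and 5-Aza. Quantile normalization gave 757 genes for 5-Aza in B2-1, and the cause was not tested.

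No label pairs the libraries by replicate number. The correlation of replicate differences between groups ran from -0.127 to 0.212 in the first deposit (median 0.007) and -0.032 to 0.143 in the second (median 0.008). It was highest for siKpnb1 with TSA (0.212), 5-Aza (0.198) and control (0.176), so some pairing of these is not excluded. A fit with replicate number as a block gave 539, 193, 1346, 2262, 3322, 1691, 100, 655, 1404, 209, 630 and 1824 genes, in the same order.

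Among the genes named in the report, no called change reversed under any alternative. 3326 values stayed on their side of the threshold, 11 lost the call and 8 gained it. With an estimated correlation between genes 95 list tests lost their call and 138 did not change sides. All 30 correlations over fewer genes were within 0.1 of the reported ones. With 1 control library for each of 2 comparisons, in both ways, 19 of 22 were, and those that moved were siCse1l with siKpnb1 (0.647 in 1 way) and siCse1l with 5-Aza in HCT116 (0.541 and 0.536). Counts of genes silent in control rested on the limits. With limits of 0.1 and 0.5 they were 26 for siCse1l in B2-1, 18 for siKpnb1, 29 for 5-Aza, 284 for TSA, 431 for SAHA, 46 for siNova1, 122 for siCse1l in HCT116 and 59 for 5-Aza in HCT116. With 0.5 and 2 they were 34 for siCse1l in B2-1 and 13 for siKpnb1, and within 1.5 times for the other 6.

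The depth per library is unknown, which leaves the error of low values unknown too. Replicates differed by a median of 0.091 to 0.167 on the log2 scale over genes at or over 1 in both, depending on the group.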

Other observations

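These values were picked out after they were seen. In 5-Aza libraries of B2-1 cells 200 genes have a value but none in control, and 61 of them were at or over 1 FPKM in both libraries. The highest of those were PNMA5 (31.4 and 24.7 FPKM), GAGE2A (20.8 and 23.9), DAZL (15.6 and 16.6), SYCP3 (9.38 and 10.3), PAGE1 (8.48 and 8.74) and CTAG2 (7.83 and 8.69). DAZL and SYCP3 act in germ cells and GAGE2A, PAGE1 and CTAG2 belong to cancer-testis families. In the siKpnb1 libraries, which list them, PNMA5 stood at 0.079 and a listed 0, SYCP3 at 0.359 and 0.448, and the other 4 at a listed 0 in both. For siCse1l 95 genes had no control value and 20 were at or over 1 in both libraries, among them CYP4F3 (5.66 and 5.35) and DIRAS3 (3.17 and 3.38), an imprinted gene. CYP4F3 stood at 2.04 and 2.64 with siKpnb1 and DIRAS3 at 1.39 and 1.68.

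In 3 of the B2-1 file sets the genes are ordered by their change from control, with a Spearman correlation between position and change of -0.997 for siCse1l, -0.995 for SAHA and -0.992 for TSA, against -0.220 for 5-Aza and 0.033 for siKpnb1. Titles and file names of the 5-Aza libraries of B2-1 give opposite replicate numbers, and the titles were used.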
